A study of Xenopus laevis with 14 samples.

How the data were processed

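Total RNA from dissected anterior endoderm of Xenopus laevis embryos was measured on 14 Affymetrix 3' expression arrays, 6 at stage NF32 and 8 at stage NF36. The deposited values are linear probe set intensity values with 1 decimal, in 1 column per array. PLIER, an Affymetrix model that condenses the probes of a probe set into 1 intensity, is listed among the authors' processing tools. Its role and version, the scaling, the filter on probe sets and the genome build are not given in the sources used here. The deposited intensity values had means of 140.19 to 140.36 on the NF32 arrays and 100 on the NF36 arrays, so each stage had been scaled apart. Levels were therefore not compared between stages. The series description names an earlier chip for NF36 than for NF32, whereas both stages' values carry identifiers of the same chip. Which chip the NF36 arrays used was left open.

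Of 24218 probe sets, 22251 had values at both stages, 604 at NF32 alone and 1363 at NF36 alone. All 22855 probe sets of NF32 and all 23614 of NF36 were tested, including 10 reporter controls. The platform annotation gave exactly 1 gene symbol to 12186 probe sets at NF32 and 12581 at NF36, which name 9260 and 9594 genes. It gave several symbols to 231 and 237, and none to 10438 and 10796. Symbols ending in .L and .S are copies of a gene on the 2 subgenomes of this species, and whether a probe set reads only 1 copy was not tested. Chromosome positions were not used here.

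Values were taken as log2(value + 16), which draws the changes of dim probe sets toward 0, so their folds are understated. No further normalization was applied. Ptf1a and GFP arrays of each stage were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided). Benjamini-Hochberg adjusted p under 0.05 over all probe sets of the stage was the threshold. Changes are Ptf1a minus GFP. The difference of the Ptf1a effect between stages was a contrast in 1 limma fit of 9139 genes measured at both stages, with 1 probe set per gene and stage, the one with the highest mean. Genes past the threshold at both stages were compared with the number expected of independent calls by Fisher's exact test in R 4.3.3. Genes are not independent replicates in that test.

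Gene lists were tested with camera from limma at its preset correlation of 0.01, over lists with at least 5 measured genes and 1 probe set per gene. Adjusted p was taken over the lists of a stage. 17 lists were written before the data were examined: pancreatic progenitor factors, exocrine and endocrine genes, the Notch pathway, a Ptf1a neural programme, neuronal, liver, gut and stomach, skeletal muscle, heart and smooth muscle, blood cell, endothelial and epidermis markers, yolk and maternal genes of endoderm, the secretory pathway, cell cycle, and cell cycle exit with the p53 response. The 8 marker lists cover cells that dissected endoderm could hold beside pancreas. A further 7 lists were chosen after a first look at the genes that changed most: innate immune, neural progenitor, retina and lens, interferon, FOXO and fasting, glucocorticoid, and abundant larval epidermis genes. Camera was repeated with the correlation estimated per list, and fry was run beside it.

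Numbered GFP and Ptf1a samples of a stage came from the same batch of embryos per the labels. As a check, each array's departure from its group mean was correlated with that of its partner across probe sets. Pearson's r was 0.711, 0.297 and 0.416 for the 3 pairs of NF32 and 0.765, 0.670, 0.717 and 0.639 for the 4 pairs of NF36, in each case above that of every other pairing. These are correlations across probe sets, which are not independent replicates. The fit chosen before the data were examined had no pair term, so values with the replicate as a block are given beside a result where they change its call or move a count by over 1.5 times.

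Named genes followed a rule written before the data were examined. At each stage it takes ptf1a, and the 15 largest rises and 15 largest falls among genes past the threshold whose groups did not overlap and whose higher group lay above the median of all probe sets. It adds up to 6 genes past the threshold of each list, by p, or the 2 with the smallest p where fewer than 2 passed. It also takes the 12 largest changes shared by the stages, the 10 largest differences between stages, and up to 2 unnamed probe sets per direction. A gene read by several probe sets is given by the one with the smallest p, or in list counts by the one with the highest mean. Members of the added lists were taken by the list part of the rule.

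The alternatives tried were offsets of 1 and 64, quantile normalization, median centring, leaving out probe sets below the 40th percentile of the stage, the replicate block, eBayes with trend and robust settings, array weights (statmod 1.5.0), a 2-fold minimum, the mean over a gene's probe sets, shared probe set identifiers, both other list tests, and leaving out each array in turn. Every split of the arrays into groups of the real sizes was also fitted, 10 at NF32 and 35 at NF36, and 100 drawn splits for results that use both stages. Bootstrap intervals at 95% used 10000 draws of genes. They leave out the spread between arrays, and genes are not independent replicates in them. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9. Spearman's rho between the arrays of the 2 stages was taken with scipy 1.17.1.

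The fit was tested on simulated data of the same size, with known changes in probe sets above the median level. At NF32 it recovered 38.8% of simulated log2 changes of 0.5 and 100% of those of 1 and 2, with 4 false calls of 163. At NF36 it recovered 97% at 0.5, 98.5% at 1 and 100% at 2, with 2 false calls of 199. Simulated pair effects had the same SD as the noise of single arrays. The real NF36 pairs correlated at 0.639 to 0.765, so the simulated pairing may be too weak there. Recovery without the block may then be overstated. With the replicate block, 23 of 214 calls at NF32 and 22 of 221 at NF36 were false, a share above the 5% aimed at. The list tests found the 1 shifted list at each stage and called no other, with genes simulated as independent. The number of arrays limits the precision of every value.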

Results

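Gene expression was measured in anterior endoderm, the embryonic tissue that gives rise to pancreas, liver, stomach and duodenum, dissected from Xenopus laevis embryos. The embryos had received 400 pg of GFP mRNA alone or together with 800 pg of Ptf1a mRNA. Ptf1a is a transcription factor needed to form exocrine pancreas and inhibitory neurons. 3 arrays per group were made at stage NF32 and 4 per group at NF36, both tailbud stages, each from about 15 pooled explants. The total amount of injected mRNA differed between the groups along with Ptf1a. Array means were 140.19 to 140.36 at NF32 over 22855 probe sets and 100 at NF36 over 23614. Between 13.0% and 15.1% of probe sets read below 16 on the NF32 arrays, and between 25.4% and 27.5% on the NF36 arrays. The comparisons ask which genes lie downstream of Ptf1a at these stages. Intensities are given as mean ± SD of the arrays of a group and changes as log2 change ± SE, Ptf1a minus GFP.

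At NF32, Ptf1a explants had higher levels of neuronal genes than GFP explants. The ptf1a probe set rose from 13.6 ± 5.41 to 314 ± 92.7 (SD, n = 3 each, log2 change 3.45 ± 0.24, adjusted p = 0.00147). Whether it reads the injected mRNA, the embryo's own transcript or both is not given in the sources used here. Of the 39 measured neuronal markers, 20 passed the threshold, all higher, 29 passed adjusted over the list alone, and all 39 had a change above 0. Their median log2 change was 0.62 (camera adjusted p = 1.29e-29, adjusted p = 0.126 with an estimated correlation). The growth cone protein gene stmn2.L rose from 3.63 ± 2.17 to 121 ± 15.3 (2.80 ± 0.12, adjusted p = 0.00073). The neuronal RNA-binding protein gene elavl4.L rose from 15.5 ± 5.08 to 200.3 ± 35.0 (2.78 ± 0.17), and the neuronal tubulin tubb3.L from 21.9 ± 7.74 to 189 ± 19.7 (2.45 ± 0.16). The more abundant tubulin tubb2b.S went from 290.0 ± 20.1 to 646 ± 14.2 (1.12 ± 0.08). Also higher were dpysl3.L (2.22 ± 0.13), the synaptic gene snap25.L (1.78 ± 0.13) and, outside the list, the neuronal filament gene prph.S (3.16 ± 0.21). These 8 genes passed in all 6 fits that left out 1 array.

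Lists of genes used by neurons and by endocrine cells moved in the same direction at NF32. In the Ptf1a neural programme, genes that act with Ptf1a in the nervous system, 3 of 14 passed, all higher, 4 adjusted over the list alone and 5 with the replicate block. They were slc32a1.S, which loads inhibitory transmitters into vesicles (0.40 ± 0.07), kirrel2.L (0.78 ± 0.14) and lhx1.L (0.46 ± 0.09), and the list median was 0.24 (camera adjusted p = 8.65e-05, adjusted p = 0.165 with an estimated correlation). The 3 calls held in 0, 1 and 0 of the 6 fits that left out 1 array. Without dim probe sets the list did not pass (camera adjusted p = 0.0521, median 0.17), and of its members slc32a1.S read 1.5 in GFP and 7.07 in Ptf1a explants and lhx1.L 11.6 and 21.8. In the Notch pathway, 4 of 22 genes passed, all higher, with 13 adjusted over the list alone and 13 with the block (median 0.41, camera adjusted p = 2.97e-09, adjusted p = 0.165 with an estimated correlation). They were the Notch target genes hes5.2.L (1.11 ± 0.18), hey1.S (1.07 ± 0.17), nrarp.S (0.77 ± 0.13) and hes5.1.S (0.71 ± 0.11). These calls held in 1, 3, 1 and 1 of the 6 fits that left out 1 array. Of 23 endocrine genes 4 were higher and none lower, 11 higher and 2 lower adjusted over the list alone, 10 and 2 with the block (median 0.42, camera adjusted p = 9.39e-07, adjusted p = 0.165 with an estimated correlation). The 4 were syt4.L (1.63 ± 0.17), the prohormone processing genes cpe.L (0.96 ± 0.10) and cpe.S (0.98 ± 0.16), and pcsk2.L (0.53 ± 0.10), which neurons also express. The endocrine list did not pass without dim probe sets (camera adjusted p = 0.165), though its median was then 0.50. Of 23 genes of cell cycle exit and the p53 response, gadd45g.L (1.27 ± 0.17) and btg2.S (0.92 ± 0.13) passed, 8 adjusted over the list alone and 6 with the block, all higher (median 0.26, camera adjusted p = 1.94e-07, adjusted p = 0.165 with an estimated correlation). No cell cycle gene passed in limma among 78 over all probe sets, adjusted over the list alone, with the block or at an unadjusted p under 0.05. The 2 with the smallest p were ccnb3.S (0.27 ± 0.11, adjusted p = 0.314) and ube2c.S (0.18 ± 0.08, adjusted p = 0.321).

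Blood and heart genes were lower in the Ptf1a explants at NF32. Of 22 blood cell markers, 11 passed lower and 1 (nfe2.S, of which another probe set passed lower) higher, 17 and 1 adjusted over the list alone (median -0.93, camera adjusted p = 7.70e-11, adjusted p = 0.126 with an estimated correlation). The haemoglobin gene hba2.L fell from 852 ± 439 to 33.6 ± 29.7 (-4.25 ± 0.64, adjusted p = 0.0207) and hbe1.L fell by 3.81 on the log2 scale, each passing in 3 of 6 fits that left out 1 array. The globin probe sets may not tell related genes apart. The granulocyte enzyme mpo.L fell from 463 ± 68.3 to 40.4 ± 20.8 (-3.15 ± 0.29, adjusted p = 0.00397), and the granule protein genes prtn3.S (-3.10 ± 0.17) and epx.L (-2.88 ± 0.24) fell with it. Lower too were alas2.L, an enzyme of haem synthesis (-1.82 ± 0.21), and the leukocyte gene lcp1.S (-1.81 ± 0.20). Of 26 heart and smooth muscle markers, 11 passed lower and 1, bmp4.L (0.49), higher, 15 and 3 adjusted over the list alone (median -0.47, camera adjusted p = 3.72e-09, adjusted p = 0.126 with an estimated correlation). Cardiac troponin tnnc1.L fell from 174 ± 12.9 to 37.5 ± 3.28 (-1.83 ± 0.09, adjusted p = 7.48e-04), cardiac myosin myh6.S from 310 ± 48.3 to 57.3 ± 9.16 (-2.15 ± 0.14), and atrial myosin light chain mylc2a from 228 ± 46.8 to 36.9 ± 8.26 (-2.20 ± 0.17). A brighter mylc2a probe set fell less (-1.28 ± 0.18, adjusted p = 0.0149). bmp4.L and nfe2.S are named after their values were seen.

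At NF32, 30 of 35 skeletal muscle markers had a change above 0 (median 0.85, camera adjusted p = 2.19e-07, adjusted p = 0.345 with an estimated correlation). None passed higher over all probe sets in limma, against 19 adjusted over the list alone, 3 with the block and 20 at an unadjusted p under 0.05. The 2 that passed were lower: actn2.S (-1.18 ± 0.11, adjusted p = 0.00483) and smyd1.L (-1.16 ± 0.21, adjusted p = 0.0364), both of which heart muscle also expresses. Among 20 epidermis markers, the keratin krt70.L passed, higher (1.16 ± 0.16), both over all probe sets and adjusted over the list alone (median 0.09, camera adjusted p = 0.0788, adjusted p = 0.63 with an estimated correlation). Without GFP replicate 3 or Ptf1a replicate 1, the epidermis list passed (camera adjusted p = 0.0110 and 0.00191). None of 11 endothelial markers passed in limma over all probe sets, adjusted over the list alone or with the block, against 2 at an unadjusted p under 0.05 (median 0.07, camera adjusted p = 0.231, and 0.0443 without dim probe sets). fli1.S (0.26 ± 0.08) and aplnr.S (0.27 ± 0.09) had its smallest p.

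Pancreatic progenitor factors went both ways at NF32, and gut and liver markers were lower. Of 25 pancreatic progenitor factors, ptf1a, sox9.L (0.60 ± 0.08) and the motor neuron and beta cell factor mnx1.L (0.62 ± 0.10) were higher, whereas the endoderm factors foxa1.L (255 ± 18.2 to 153 ± 22, -0.69 ± 0.11) and gata6.L (-0.50 ± 0.08) were lower. ptf1a passed in all 6 fits that left out 1 array, and sox9.L, mnx1.L, foxa1.L and gata6.L in 5, 1, 1 and 0. Adjusted over the list alone 5 passed each way, with the block 5 and 6, and the list did not pass (median 0.01, camera adjusted p = 0.822). Of 12 exocrine genes only the procarboxypeptidase gene cpa1.L passed, from 2.60 ± 1.75 to 38.1 ± 21.4 (1.47 ± 0.26, adjusted p = 0.0343, in 2 of 6 fits that left out 1 array). Adjusted over the list alone 1 was higher and 1 lower, as with the block, where nr5a2.S (-0.50) passed at adjusted p = 0.0448 against 0.0929 without. The exocrine median was -0.03 and its mean 0.04 (camera adjusted p = 0.961). Gut and stomach markers were lower for 2 of 21, also 2 adjusted over the list alone, and 5 with the block: cndp2.L (-0.64 ± 0.09) and sfrp5.S (-0.70 ± 0.12) (median -0.18, camera adjusted p = 0.00429, adjusted p = 0.126 with an estimated correlation). Of 39 liver markers the plasma protein gene itih2.S passed (-1.17 ± 0.19), 1 higher and 7 lower adjusted over the list alone, 4 and 11 with the block (median -0.35, camera adjusted p = 0.00727, adjusted p = 0.588 with an estimated correlation). serpina1.L (-1.31 ± 0.30) had adjusted p = 0.0739, and 0.00692 with the block. The liver list did not pass without GFP replicate 1 (camera adjusted p = 0.177, median -0.30) or without dim probe sets (0.0521, median -0.31).

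The secretory pathway list at NF32 had no gene past the limma threshold among 79, over all probe sets or adjusted over the list alone, with 3 lower in the block fit and 1 higher and 9 lower at an unadjusted p under 0.05 (median -0.10, camera adjusted p = 0.00122, adjusted p = 0.577 with an estimated correlation). Its smallest p belonged to dnajb11.S (-0.45 ± 0.11, adjusted p = 0.0961, and 0.0415 with the block) and ddit3.L (0.31 ± 0.09, adjusted p = 0.122). None of 8 yolk and maternal genes passed in limma over all probe sets, adjusted over the list alone or at an unadjusted p under 0.05, and 1 was lower with the block (median -0.04, camera adjusted p = 0.961). ddx4.L (-0.47 ± 0.21) had adjusted p = 0.341, and 0.0110 with the block, and a2m.S (0.18 ± 0.10) had adjusted p = 0.454.

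The largest rises at NF32 also held secreted and enzyme genes of no list fixed beforehand. phyhdlb.L rose from 31.2 ± 10.7 to 995 ± 399 (4.38 ± 0.29, adjusted p = 0.00123). The chemokine gene cxcl8.L, whose product attracts neutrophils, rose from 69.9 ± 52.7 to 895 ± 237 (3.59 ± 0.47, adjusted p = 0.0135), and the cytokine gene il1b.S from 29.1 ± 31.8 to 410 ± 201 (3.41 ± 0.56, adjusted p = 0.0268). They passed in 4 and 2 of the 6 fits that left out 1 array. The collagenase genes mmp8.L (4.24 ± 0.59) and mmp1.S (2.60 ± 0.24), acod1lb.L (3.53 ± 0.34), satpb.L (3.31 ± 0.45), tlrs5.L (3.11 ± 0.47), fabp7.L (2.68 ± 0.43) and thbs4.S (2.46 ± 0.29) were higher as well. Further large falls were those of hba-l5.L (-3.56 ± 0.61), hba3.L (-3.15 ± 0.57), hba4.S (-2.82 ± 0.54), mmp9.1.S (-2.46 ± 0.23), mpo.S (-2.44 ± 0.43), the retinol-binding gene rbp2.L (-2.37 ± 0.45), prss57.L (-2.25 ± 0.20) and tnni3.S (-1.97 ± 0.17). Unnamed probe sets with the smallest p were Xl2.51820.2.S1_at and Xl2.12377.1.A1_at, higher, and Xl2.1097.1.S1_x_at and Xl2.2412.1.S1_at, lower.

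In all, 723 of 22855 probe sets passed at NF32, 449 higher and 274 lower, of which 134 and 104 changed at least 2-fold. 11 of the 17 lists passed in camera with the preset correlation, 6 higher and 5 lower, 8 in fry and none with an estimated correlation, where 5 had an unadjusted p under 0.05. With the replicate block 2107 passed, 1149 higher and 958 lower, and without 1 array 390 (GFP replicate 1), 181 (GFP replicate 2), 430 (Ptf1a replicate 1), 369 (Ptf1a replicate 2) or 304 (Ptf1a replicate 3). For every named gene past the threshold all 3 Ptf1a arrays lay beyond all 3 GFP arrays, and of 81 such calls 28, 44, 21, 26, 24 and 32 ended without GFP replicate 1, 2 or 3 and Ptf1a replicate 1, 2 or 3.

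**Figure D1:**
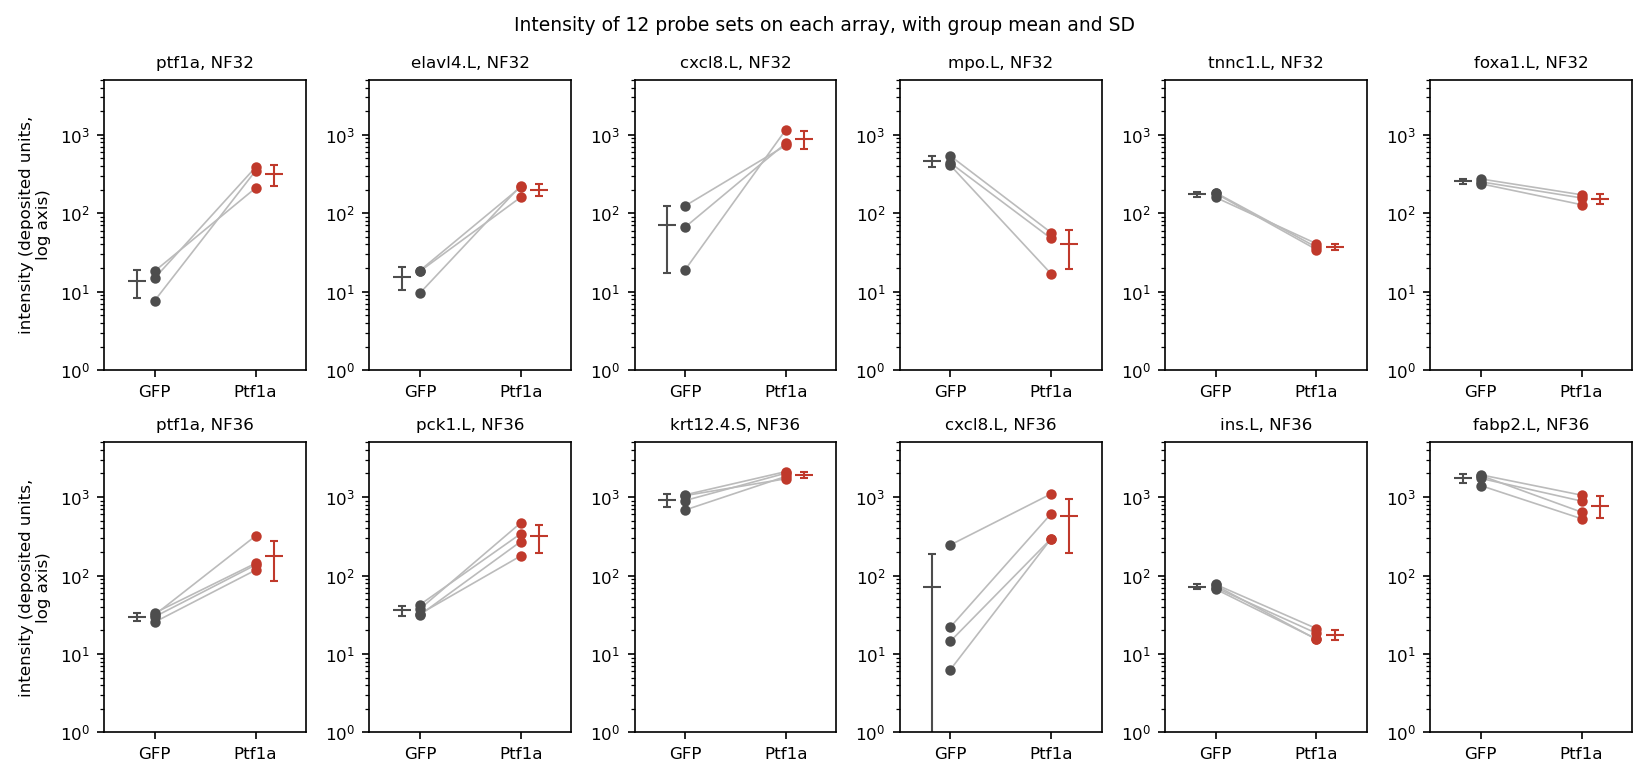
Deposited intensity (log axis) of 6 probe sets at each stage on every GFP and Ptf1a array; grey lines join arrays of the same replicate number, and bars give the group mean and SD. At NF32 elavl4.L rose to 200.3 and tnnc1.L fell to 37.5; at NF36 ins.L fell to 17.6, and the lower SD bar of cxcl8.L in GFP (72.0 ± 116) runs off the axis.

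At NF36, insulin RNA was lower in Ptf1a explants while epidermis markers and 3 genes of glucose-making enzymes were higher. The insulin genes ins.L and ins.S fell from 72.4 ± 4.57 to 17.6 ± 2.72 (SD, n = 4 each, log2 change -1.40 ± 0.07, adjusted p = 6.77e-04) and from 96.3 ± 10.7 to 30.3 ± 8.75 (-1.29 ± 0.14, adjusted p = 0.00434). pck1.L, which encodes a rate-limiting enzyme of glucose synthesis, rose from 35.9 ± 5.07 to 315 ± 123 (2.60 ± 0.24, adjusted p = 0.00351), with pck1.S (1.87 ± 0.22) and glucose-6-phosphatase g6pc1.1.L (2.02 ± 0.36). The binding protein gene igfbp1.S, which insulin represses in liver, rose from 87.3 ± 6.46 to 332 ± 61.0 (1.74 ± 0.13, adjusted p = 0.0018), and igfbp1.L rose as well (1.25 ± 0.12). The ptf1a probe set rose from 30.0 ± 3.34 to 179 ± 94.2 (1.98 ± 0.26, adjusted p = 0.00727). All of these passed in all 8 fits that left out 1 array, except g6pc1.1.L, which passed in 6.

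Epidermis markers moved together at NF36. Of 20 measured, 14 passed, all higher, 18 adjusted over the list alone, and all 20 had a change above 0 (median 0.90, camera adjusted p = 2.03e-15, adjusted p = 0.138 with an estimated correlation). The keratin krt12.4.S rose from 925 ± 176 to 1920 ± 180 (1.06 ± 0.14, adjusted p = 0.0079). The junction gene cldn4.L (1.41 ± 0.17), the cornified envelope gene evpl.L (1.36 ± 0.20), upk1b.L (0.98 ± 0.16) and the epidermal factors grhl3.S (0.93 ± 0.10) and grhl1.L (0.39 ± 0.06) were also higher. The proton pump gene atp12a.L rose among the largest changes (1.72 ± 0.22). The shift of epidermis markers was in the same 4 Ptf1a arrays as the other changes of NF36.

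Factors of pancreas and of endocrine cells went both ways at NF36. Of 25 pancreatic progenitor factors 4 were higher, ptf1a, sox9.S (66.9 ± 11.1 to 175 ± 29.0, 1.21 ± 0.13), sox9.L (0.84 ± 0.08) and gata4.S (0.34 ± 0.07). 2 were lower, nkx6-2.L (129 ± 11.5 to 69.0 ± 9.56, -0.78 ± 0.10) and hnf4a.S (-0.42 ± 0.10). gata4.S passed in 2 and hnf4a.S in 1 of the 8 fits that left out 1 array, and the others in all 8. Adjusted over the list alone 4 were higher and 3 lower, with the block 5 and 7, and the list did not pass (median 0.02, camera adjusted p = 0.579). Of 24 endocrine genes, the factors neurod1.S (0.98 ± 0.16) and neurod1.L (0.66 ± 0.13) were higher, and ins.L, ins.S and tm4sf4.L (-0.91 ± 0.18) were lower. Both neurod1 genes were dim: neurod1.S read 4.3 in GFP and 24.4 in Ptf1a explants, and neurod1.L 2.1 and 13.1. They passed in 6 and 2 of the 8 fits that left out 1 array, and tm4sf4.L in 3. Adjusted over the list alone 5 passed each way, with the block 5 higher and 4 lower (median 0.08, camera adjusted p = 0.579). Of 25 exocrine genes cpa1.L passed, from 8.32 ± 2.73 to 25.4 ± 3.70 (0.77 ± 0.10, adjusted p = 0.00671), 1 adjusted over the list alone and 4 with the block, all higher. The exocrine list did not pass (median 0.04, camera adjusted p = 0.128), but passed without Ptf1a replicate 4 (camera adjusted p = 0.0181). cel.2.S (0.50 ± 0.13) had adjusted p = 0.0647, and 0.0223 with the block.

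Signalling, neuronal and stress lists were higher at NF36. In the Notch pathway 7 of 22 genes passed, all higher, 12 higher and 2 lower adjusted over the list alone, 11 and 2 with the block (median 0.23, camera adjusted p = 4.54e-05, adjusted p = 0.301 with an estimated correlation). Among them were the receptor gene notch1.S (0.50 ± 0.07), the ligand gene jag1.L (0.51 ± 0.08), and the target genes hey1.S (1.06 ± 0.17), hes5.1.L (0.63 ± 0.12), hes5.2.L (0.62 ± 0.13) and hes4.S (0.56 ± 0.13). Of 23 genes of cell cycle exit and the p53 response 6 passed, all higher, 13 adjusted over the list alone and 14 with the block, with sesn1.L (1.05 ± 0.14) and gadd45g.S (0.91 ± 0.14) first by p, then btg2.S, gadd45a.S, gadd45g.L and ccng2.L (median 0.31, camera adjusted p = 1.14e-07, adjusted p = 0.179 with an estimated correlation). Neuronal markers were higher for 5 of 38, 10 adjusted over the list alone, with 14 higher and 3 lower with the block (median 0.22, camera adjusted p = 1.23e-05, adjusted p = 0.398 with an estimated correlation). tubb2b.S rose from 197 ± 4.90 to 323 ± 37.6 (0.66 ± 0.09) and syt1.L by 0.55 ± 0.09, beside the dim genes elavl3.L (0.42), sox3.S (0.43) and ebf2.S (0.73). Without dim probe sets the neuronal list did not pass (camera adjusted p = 0.0845, median 0.06). In the Ptf1a neural programme 3 of 12 passed, all higher, 3 adjusted over the list alone and 5 with the block: tfap2a.S (0.97 ± 0.14), tfap2a.L (0.80 ± 0.13) and kirrel2.L (0.95 ± 0.16) (median 0.19, camera adjusted p = 7.16e-04, adjusted p = 0.138 with an estimated correlation). tfap2a is also an epidermal and neural crest factor.

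Gut, liver and secretory genes were lower at NF36. The intestinal fatty acid binding gene fabp2.L fell from 1735 ± 237 to 780 ± 238 (-1.18 ± 0.21, adjusted p = 0.0187) and the brush border gene vil1.S by 0.96 on the log2 scale. They were the 2 of 26 gut and stomach markers that passed, both lower, 7 adjusted over the list alone, 2 higher and 12 lower with the block (median -0.19, camera adjusted p = 7.16e-04, adjusted p = 0.203 with an estimated correlation). Of 45 liver markers, igfbp1.S and igfbp1.L were higher and the plasma protein genes itih2.S (-0.80 ± 0.18), serpind1.L (-0.57 ± 0.13) and f2.L (prothrombin, -0.50 ± 0.11) lower. The 3 lower calls held in 2, 1 and 1 of the 8 fits that left out 1 array. Adjusted over the list alone 2 were higher and 6 lower, with the block 3 and 17 (median -0.16, camera adjusted p = 4.89e-04, adjusted p = 0.398 with an estimated correlation). In the secretory pathway list 3 of 79 passed, all lower, 1 higher and 5 lower adjusted over the list alone, and 2 higher and 44 lower with the block (median -0.20, camera adjusted p = 1.32e-09, adjusted p = 0.203 with an estimated correlation). They were the chaperone genes hsp90b1.L (1248 ± 140 to 798 ± 139, -0.65 ± 0.13) and calr.L (-0.45 ± 0.09), and sec11a.L (-0.25 ± 0.06). These 3 calls held in 2, 1 and 0 of the 8 fits that left out 1 array. Other large falls were ctse.L, a protease of stomach lining (232 ± 32.5 to 49.6 ± 12.3, -1.93 ± 0.15), rbp2.L (1358 ± 205 to 406 ± 270, -1.88 ± 0.36), gsta1.L (-1.70 ± 0.17), adhfe1.S (-1.56 ± 0.32), the iodide transporter slc5a5.L (-1.37 ± 0.26), dhrs11.S (-1.37 ± 0.12), the bile acid enzyme cyp8b1.1.S (-1.15 ± 0.25) and cbx6.L (-1.11 ± 0.13).

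Blood markers were again lower at NF36, for 3 of 27, with 1 higher and 15 lower adjusted over the list alone and 2 and 17 with the block (median -0.51, camera adjusted p = 6.60e-07, adjusted p = 0.301 with an estimated correlation). They were mpo.L (291 ± 44.4 to 129 ± 54.6, -1.14 ± 0.23, adjusted p = 0.0292), lcp1.S (-0.85 ± 0.14) and gata1.S (-0.51 ± 0.12), and the granule genes prtn3.L (-1.37 ± 0.29), prtn3.S (-1.36 ± 0.29) and epx.L (-1.18 ± 0.23) fell too. lcp1.S passed in all 8 fits that left out 1 array, prtn3.L and epx.L in 2 each, and mpo.L, gata1.S and prtn3.S in 1 each. Heart and smooth muscle markers were higher for 3 of 29, also 3 adjusted over the list alone, with 5 higher and 3 lower with the block (median 0.54, camera adjusted p = 2.16e-04, adjusted p = 0.398 with an estimated correlation). The 3 were bmp4.S (0.85 ± 0.11), bmp4.L (0.70 ± 0.09) and myl9.S (0.54 ± 0.10), which are not restricted to heart: bmp4 is a growth factor of many tissues and myl9 a myosin light chain of smooth muscle. Skeletal muscle markers had 1 higher, pgam2.L (1.05 ± 0.23), and 2 lower, the muscle factors myog.S (-0.83 ± 0.18) and myog.L (-0.51 ± 0.10), of 37. Adjusted over the list alone 3 passed each way, and 6 higher and 3 lower with the block (median 0.42, camera adjusted p = 0.00214, adjusted p = 0.398 with an estimated correlation).

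No gene passed in limma at NF36 in 3 lists, where 1 cell cycle, 2 endothelial and 1 yolk or maternal gene had an unadjusted p under 0.05, all higher. Of 77 cell cycle genes 5 higher and 1 lower passed with the block and none adjusted over the list alone (median 0.03, camera adjusted p = 0.365, and 0.0396 without Ptf1a replicate 1). kif11.L (0.39 ± 0.13) had adjusted p = 0.122, and 0.00479 with the block, and espl1.S (0.17 ± 0.08) 0.275, and 0.0269 with the block. Of 11 endothelial markers 2 passed adjusted over the list alone and 3 with the block, all higher (median 0.06, camera adjusted p = 0.171). sox7.L (0.26 ± 0.07) had adjusted p = 0.0568, and 0.00805 with the block, and fli1.S (0.29 ± 0.08) 0.0731, and 0.0205 with the block. Of 10 yolk and maternal genes none passed adjusted over the list alone, and 1 each way did with the block (median 0.01, mean -0.0069, camera adjusted p = 0.938). vegt.L (0.20 ± 0.08) had adjusted p = 0.187, and 0.0283 with the block, and grip2.L (-0.22 ± 0.10) 0.261, and 0.0287 with the block.

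Among the largest rises at NF36, beside pck1.L, were those of acod1lb.L (3.47 ± 0.74, adjusted p = 0.0343), cxcl8.L (72.0 ± 116 to 576 ± 380, 3.32 ± 0.77, adjusted p = 0.0444), il1b.S (2.87 ± 0.56, adjusted p = 0.0254), satpb.L (2.76 ± 0.63) and the collagenase mmp1.S (2.59 ± 0.51). GFP replicate 1 stood apart from the other 3 GFP arrays for these 5 genes, and they passed in 2, 1, 3, 2 and 2 of the 8 fits that left out 1 array. Higher too were azin2.S (2.05 ± 0.35), the glutamine synthetase-like gene glul-like.1.L (1.86 ± 0.28), irf1.L (1.84 ± 0.33) and timp-1.L (1.76 ± 0.33). Unnamed probe sets with the smallest p were Xl2.41444.1.S1_at and Xl2.54737.1.S1_a_at, higher, and Xl2.26399.1.A1_at and Xl2.5116.2.A1_at, lower.

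Altogether 1294 of 23614 probe sets passed at NF36, 848 higher and 446 lower, of which 162 and 45 changed at least 2-fold, and 11 of 17 lists passed in camera, 7 higher and 4 lower, 7 in fry and none with an estimated correlation, where 3 had an unadjusted p under 0.05. With the replicate block 5531 passed, 2977 higher and 2554 lower, and with median centring 57.9% of the calls were higher. Without 1 array there were 758, 471, 471 and 584 (GFP replicates 1 to 4), 588 (Ptf1a replicate 2) or 408 (Ptf1a replicate 4). For every named gene past the threshold all 4 Ptf1a arrays lay beyond all 4 GFP arrays, and of 100 such calls 32, 47, 52 and 37 ended without GFP replicates 1 to 4 and 24, 38, 6 and 50 without Ptf1a replicates 1 to 4.

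**Figure D2:**
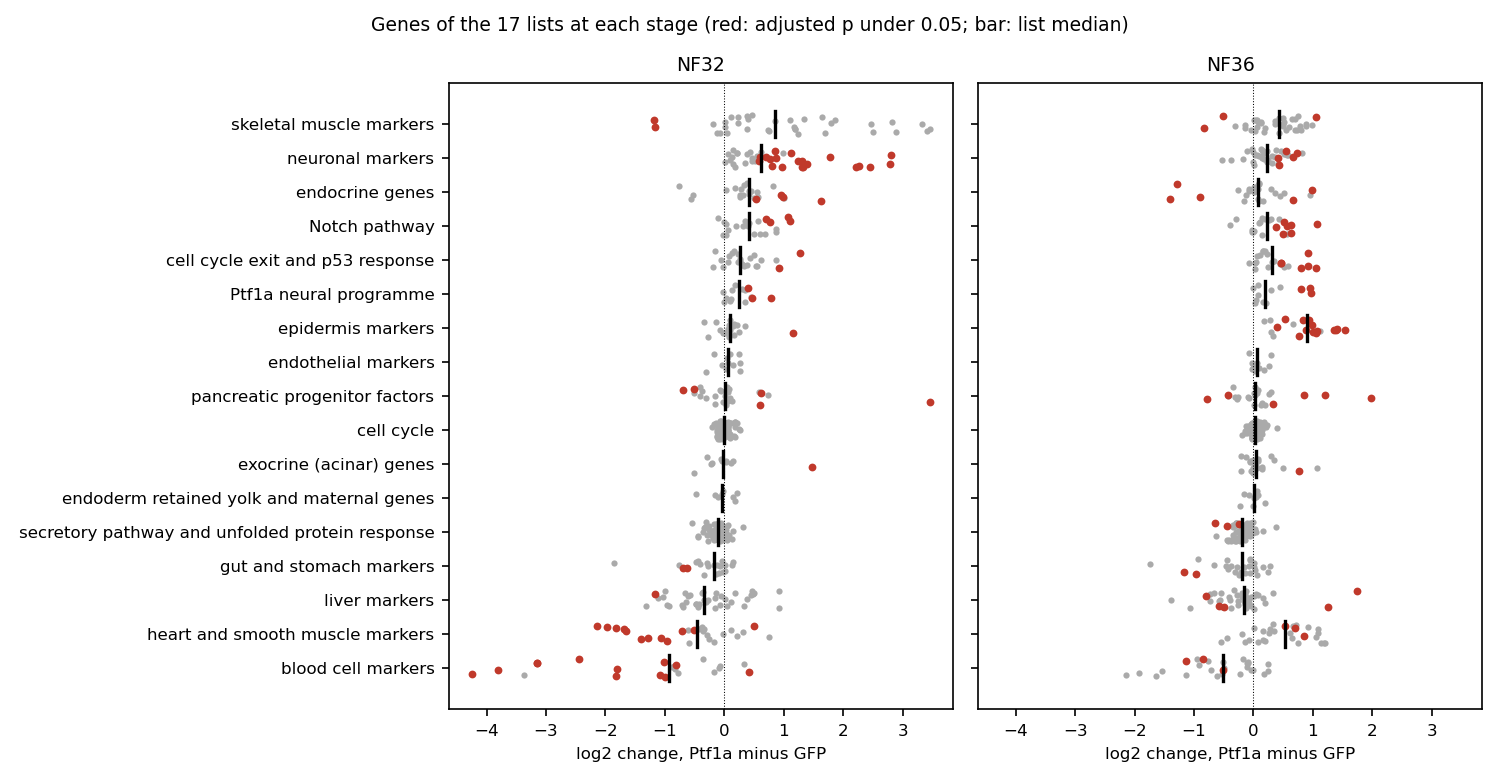
Log2 change (Ptf1a minus GFP) of each measured gene of the 17 lists at NF32 (left) and NF36 (right); red points passed the threshold over all probe sets and black bars are list medians. The neuronal median is 0.62 at NF32 and 0.22 at NF36, and the epidermis median 0.09 and 0.90.

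Across stages, many of the same genes changed. Of 9139 genes measured at both, 66 were higher and 36 lower at both stages, against 9.25 and 3.10 expected of independent calls (Fisher's exact p = 2.47e-39 and 6.35e-29), and none passed in opposite directions, against 10.9 expected. Over all these genes the changes correlated with Pearson's r of 0.578 and Spearman's rho of 0.540, across genes, which are not independent replicates. Of the 847 genes past the threshold at either stage 82.8% had the same sign at both, against 70.6% of all 9139. The largest shared rises were acod1lb.L, cxcl8.L, il1b.S, satpb.L, ptf1a, mmp1.S, prph.S and prph.L. prtn3.S, mpo.L, rbp2.L and epx.L had the largest shared falls. The change of ptf1a was smaller at NF36 by -1.47 ± 0.39, which did not pass (adjusted p = 0.112). For insulin the falls at NF32 did not pass (ins.L -0.76, adjusted p = 0.0951, and ins.S -0.56, adjusted p = 0.294), nor did their difference from NF36 (adjusted p = 0.211 and 0.347).

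The Ptf1a effect differed between stages for 116 genes, 67 with a higher and 49 with a lower change at NF36. The stages were scaled apart and their chips may have differed, and neither can be told apart from stage in these differences. At the lower scale of NF36 the same offset also draws changes more toward 0. Heart genes made up much of the largest differences: myh6.S changed by -2.14 at NF32 and 1.2 at NF36 (difference 3.34 ± 0.64, adjusted p = 0.0267), tnnc1.L by -1.83 and 1.13 (2.96 ± 0.58, adjusted p = 0.0306), with tnni3.S (3.06), tnni3.L (2.74), mylc2a (2.63), acta2.L (2.15) and hspb7.L (2.09). Their rises at NF36 did not pass at that stage (myh6.S adjusted p = 0.223). The mylc2a difference is that of its brighter probe set, which changed by -1.28 at NF32 and 1.34 at NF36. Neuronal genes differed the other way, tubb3.L by -2.03 ± 0.22 (adjusted p = 0.00142), prph.S by -2.04 ± 0.36 (adjusted p = 0.0181) and stmn2.L by -2.80 ± 0.13 (adjusted p = 2.44e-07), the last read by a different probe set at each stage, a dim one at NF36. Of 17 lists 8 passed in camera for the difference, with a median difference of -0.48 for neuronal markers (9 of 38 genes past, camera adjusted p = 1.78e-28, adjusted p = 0.0614 with an estimated correlation), 0.71 for heart markers (5 of 26, 1.07e-16, adjusted p = 0.0974 with an estimated correlation), 0.89 for epidermis markers (2 of 19, 3.21e-15, adjusted p = 0.0842 with an estimated correlation) and -0.43 for endocrine genes (3 of 23, 4.25e-09, adjusted p = 0.0904 with an estimated correlation). The other 4 were skeletal muscle (-0.55, 3 of 34, 1.82e-05, adjusted p = 0.409 with an estimated correlation), blood (0.35, 2 of 22, 1.58e-05, 0.288), Notch (-0.19, none of 22, 2.41e-04, 0.397) and the secretory pathway (-0.08, none of 78, 2.59e-04, 0.409).

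With the replicate block the effect differed for 566 genes and 605 passed at both stages, against 102 without. Leaving out 1 array gave differences for 29 (NF32 GFP replicate 2), 42 (NF32 GFP replicate 3), 32 (NF32 Ptf1a replicate 1), 65 (NF32 Ptf1a replicate 3), 77, 77, 57 and 76 (NF36 GFP replicates 1 to 4), 182, 71 and 47 genes (NF36 Ptf1a replicates 1, 2 and 4). It left 61 and 34 genes past at both stages without NF32 GFP replicates 1 and 2, 58, 55 and 46 without NF32 Ptf1a replicates 1 to 3, 55, 42, 37 and 38 without NF36 GFP replicates 1 to 4, and 48 and 35 without NF36 Ptf1a replicates 2 and 4.

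**Figure D3:**
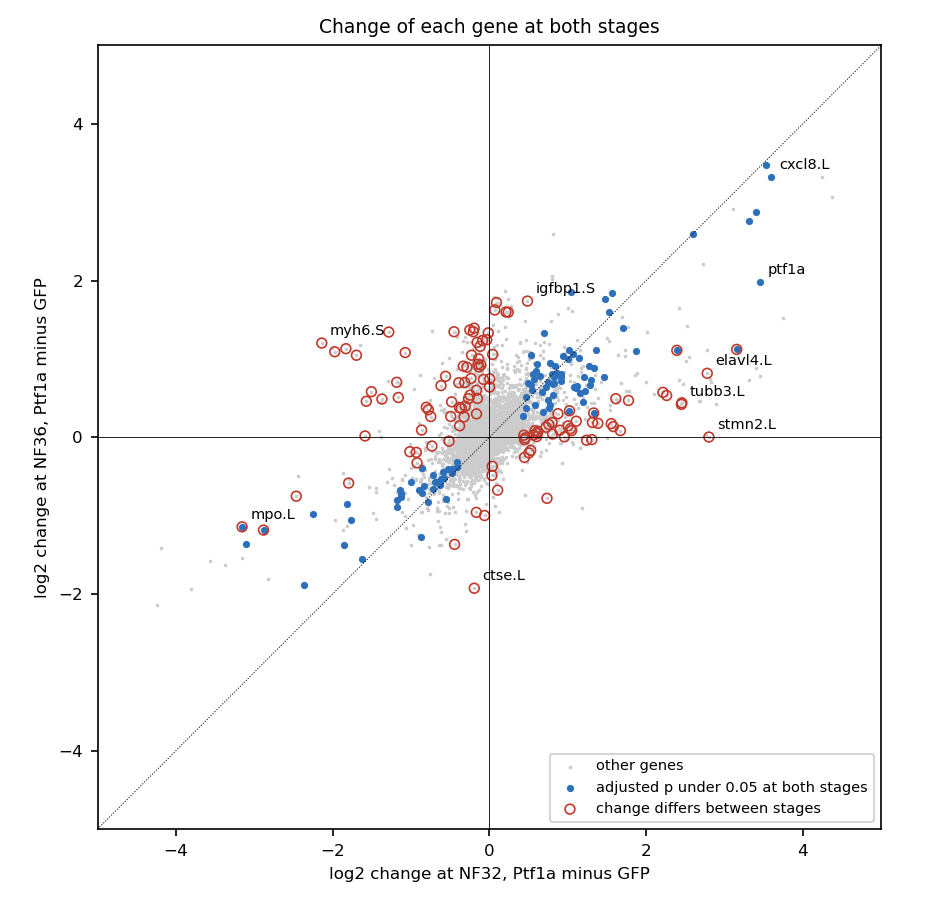
Log2 change (Ptf1a minus GFP) of each of 9139 genes at NF32 (horizontal) and NF36 (vertical), with the line of equal change dotted; blue points passed at both stages and red circles mark the 116 genes whose change differed. cxcl8.L lies near the line at 3.59 and 3.32, and myh6.S off it at -2.14 and 1.2.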

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

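The tests on heart tissue, on blood, on dilution of insulin RNA and on slower development were chosen after the results they measure were seen, and the 7 added gene lists after a first look at the genes that changed most. The other tests were chosen before the results they measure were seen.

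Neuronal genes rose more at NF32 than at NF36, though stage cannot be told apart from chip and scale in these differences. The differences of the log2 change, NF36 minus NF32, were -2.04 for prph.S (adjusted p = 0.0181), -2.03 for tubb3.L, -1.96 for elavl4.L, -1.64 for dpysl3.L, -1.31 for snap25.L and -1.28 for prph.L. That of stmn2.L (-2.80) sets a dim probe set of NF36 (11.2 in GFP) against another of NF32, and the NF32 one rose by 0.90 ± 0.34 at NF36 without passing (adjusted p = 0.187). Further named genes with a lower change at NF36 included thbs4.S (-2.02), cpe.L (-0.95), pcsk2.L (-0.70), otx1.L (-0.59621) and lhx1.L (-0.47). Neural tissue carried over with the Ptf1a explants would raise neural progenitor and regional patterning genes too. Their 20 measurable members had a median of 0.1999 (bootstrap interval 0.1316 to 0.4451), which does not part from the bound of 0.3093, which is 0.5 times the neuronal median. Some of the 20 are measurable only in Ptf1a explants, which raises that median. The 15 above 32 in GFP explants gave 0.1675 (0.0792 to 0.2859), but their baseline can hide carried-over RNA, and all 41 gave 0.2747 (0.1717 to 0.3644). Carry-over therefore cannot be told apart from a change in the cells. Markers of skeletal muscle, also foreign to endoderm, had a change above 0 in 30 of 35 at NF32 (median 0.85), with 19 higher adjusted over the list alone and none over all probe sets. Retina or lens could not be judged either: 2 genes had a median of -0.5977, and the bound set beforehand asked for no minimum number of genes. A candidate explanation is the programme that Ptf1a drives in the nervous system, whose list was higher (median 0.239, camera p = 4.07e-05, adjusted p = 0.165 with an estimated correlation) but did not pass without dim probe sets (camera adjusted p = 0.0521).

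Heart genes were lower at NF32 and higher, without passing, at NF36. The differences were 3.34 for myh6.S (adjusted p = 0.0267), 3.06 for tnni3.S, 2.96 for tnnc1.L, 2.74 for tnni3.L, 2.63 for mylc2a, 2.15 for acta2.L, 2.09 for hspb7.L, 1.88 for actn2.S and 1.67 for smyd1.L. Some myeloid genes fell more at NF32: mpo.L differed by 2.01, mmp9.1.S by 1.71, epx.L by 1.70 and ctss.S by 0.83. For mpo.S, prtn3.S, lcp1.S and prss57.L the difference did not pass in limma (adjusted p = 0.0545, 0.0569, 0.111 and 0.122). With the replicate block in limma that of prtn3.S passed (adjusted p = 0.00847). Of 22 blood cell markers 2 passed for the difference (camera adjusted p = 0.288 with an estimated correlation). Less heart tissue in the NF32 Ptf1a explants may account for part of it: 0% of 11 heart-restricted genes had a change above -0.25, and the middle 50% of their changes spans 1.2964 around a median of -1.2896. The offset draws the changes of dim genes toward 0, so that spread does not decide whether a common loss of tissue lies behind them. Less blood stays open as well, since the red cell median minus the myeloid median was -1.1322 with an interval of -2.3993 to 0.9821. The larger mRNA dose was looked for through interferon genes, whose 4 measured members had a median of -0.0494 (-0.0927 to 0.0354). With only 2 of them above a value of 32 in GFP explants, the bound set beforehand, which asked for no minimum of measurable genes, cannot exclude a dose effect, and the dose is confounded with Ptf1a.

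Insulin was lower and the fasting-type genes pck1.L, g6pc1.1.L and igfbp1.S higher at NF36, beside a rise of epidermis markers. igfbp1.S (1.25, adjusted p = 0.0177), atp12a.L (1.63), grhl3.S (1.08) and krt12.4.S (1.01) had a higher change at NF36 than at NF32. Epidermis carried over into the Ptf1a explants is a candidate source: the 22 measurable abundant larval epidermis genes had a median of 0.7439 (0.3819 to 1.0575). That value is raised by genes measurable only in Ptf1a explants, and 16 of the list's 31 genes are also in a list fixed beforehand. The 15 measured in no such list had a median of 0.3328 (0.2631 to 0.4582), and the 8 of these above 32 in GFP explants 0.2896 (0.0297 to 0.4582). These genes add only weak support to that of the epidermis markers fixed beforehand, of which all 20 had a change above 0 (median 0.90). krt12.4.S read 925 in GFP explants, so the tissue may express some itself. Dilution by such tissue is argued against as the whole cause of the insulin fall: 69 other endoderm genes (gut, liver and pancreatic progenitors) had a median of -0.1976 (-0.3503 to -0.1156), against falls of 1.40 and 1.29 for ins.L and ins.S and a bound of -0.6466. That interval comes from draws of genes, which are not independent, and leaves out the spread between arrays. A wider FOXO and fasting response remains a candidate, though small (median 0.0864, camera p = 0.0232, adjusted p = 0.278 with an estimated correlation). So does a glucocorticoid response (median 0.1939, camera p = 2.43e-04, adjusted p = 0.201 with an estimated correlation). Neither list is particular to NF36, since their medians at NF32 were 0.105 and 0.179. The insulin falls at NF32 did not pass in limma, nor did their differences from NF36 (adjusted p = 0.211 and 0.347). NF32 is therefore not shown to lack an insulin fall, and these medians do not part the lists from insulin. Of 27 FOXO genes, 16 had a change above 0 at NF36, and 7 are also in a list fixed beforehand. The FOXO and glucocorticoid responses cannot be ranked from the values here, and a direct effect of Ptf1a on endocrine cells was not tested.

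Other genes whose change differed between stages were nkx6-2.L (0.74 at NF32, -0.78 at NF36, difference -1.51, adjusted p = 0.00237), ctse.L (difference -1.73) and dhrs11.S (-0.92). Of the added lists, the immune genes mmp13.S (2.0296, adjusted p = 0.0355) and mmp3.L (1.7974, adjusted p = 0.0279) had a higher change at NF36. In all, 34 of 169 named genes measured at both stages differed.

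For the 8 NF36 arrays, 21 of 220 combinations of named probe set and group had 1 array far from the other 3, where chance gives about 1 in 20. GFP replicate 1 was high for cxcl8.L (245.3, others 6.3 to 22), acod1lb.L (92.3, others 2.6 to 9.0), il1b.S (57.3, others 3.3 to 3.8), satpb.L (56.2, others 4.2 to 5.4) and mmp1.S (48.8, others 7.4 to 13.7). Without it the log2 changes were 4.11, 4.07, 3.35, 3.21 and 2.93, against 3.32, 3.47, 2.87, 2.76 and 2.59 with all arrays. Ptf1a replicate 3 was high for ptf1a (319.4, others 117.2 to 143.1), prtn3.S (96.8, others 22.8 to 35.3) and epx.L (92.8, others 33.8 to 43.7), and low for tubb2b.S (266.5, others 337.6 to 345.1). Ptf1a replicate 1 was high for ccng2.L (124.2, others 88.8 to 93.2) and the unnamed Xl2.54737.1.S1_a_at (38.9, others 35.7 to 35.9), and Ptf1a replicate 2 low for sec11a.L (269.8, others 294.0 to 297.2). Among GFP arrays, replicate 1 was high for ccng2.L (71.8, others 64.5 to 65.2) and dusp1.S (42.5, others 28.1 to 29.2), replicate 2 for cel.2.S (24.2, others 15.5 to 16.8), sox3.S (3.7, others 1.8 to 2.1) and ebf2.S (3.7, others 2.7 to 2.8), and replicate 4 for hes5.1.L (9.7, others 7.3 to 7.6). GFP replicate 3 was low for cldn4.L (62.3, others 95 to 100.6) and sox9.L (31.7, others 40.0 to 41.4), and high for gbp1 (5.2, others 3.2 to 3.5).

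Other splits of the arrays were fitted to ask how often they give as much. At NF32 the real split gave 723 probe sets and the highest other split 1, with 1 of 10 splits as high, and for lists 11 against 13, with 4 of 10 as high. The 10 splits are too few for a share under 0.05 in the number of probe sets. For the number of NF32 lists, regrouped arrays gave as many or more, so chance is not excluded. At NF36 1 of 35 splits gave as many as the real 1294 probe sets, the highest other 112. That share does not exclude chance, since it treats paired arrays as unpaired. Every other split also holds the Ptf1a difference within its groups, so a low count there was likely beforehand. The split with 112 set pairs 1 and 4 against pairs 2 and 3. Only 8 splits part all 4 pairs, too few for a share under 0.05, and the highest other of these gave 0. For the NF36 lists 5 of 35 splits gave 11 or more, the highest 13, so chance is not excluded for the number of lists. For genes whose effect differed, 3 of 100 drawn splits gave 116 or more, the highest other 195. All 3 are among the 9 that kept the real NF32 groups, and the other 91 gave at most 35. Chance is not excluded for a regrouping of the NF36 arrays alone, and the drawn splits do not keep the pairs. For genes past at both stages 1 of 100 gave 102, the highest other 0. That comparison decides nothing for the overlap, since most other splits call few or no genes at a stage.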

How the results depend on the processing

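Every alternative named here was chosen before the data were examined, except the tests of the 7 added lists. No result of a named gene reversed under any alternative run. For named genes past the threshold this was largely fixed in advance, since their groups did not overlap and the block leaves the log2 change as it was. A count has no direction to reverse. Of 81 named genes past the threshold at NF32, 57 passed in every alternative that tested them, other than leaving out an array, and of 100 at NF36, 81 did. The dim filter left 58 and 82 of them to test, of which 44 and 68 passed throughout. 35 and 43 passed in every fit that left out an array.

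The number of probe sets past the threshold was 723 at NF32 and 1294 at NF36, the number of genes whose effect differed between stages 116, and the number past at both stages 102. Leaving out dim probe sets gave 314, 769, 47 and 61. The replicate block gave 2107, 5531, 566 and 605. A minimum change of 2-fold left 238 and 207 probe sets. An offset of 64 gave 75 genes with a differing effect and 51 past at both stages, and shared probe set identifiers gave 186 past at both. The cause of these shifts was not tested, except that the dim filter tests fewer probe sets and the fold minimum only removes calls. Leaving out 1 array gave 181 to 564 probe sets at NF32, 408 to 1344 at NF36, 29 to 182 genes with a differing effect and 34 to 128 past at both stages, with fewer arrays in each fit. The lowest of these came without NF32 GFP replicate 2 (181, 29 and 34) and NF36 Ptf1a replicate 4 (408).

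Of the 11 lists past the threshold at each stage, 0 passed at NF32 and 0 at NF36 with an estimated correlation (camera, 5 and 3 at an unadjusted p under 0.05), and 7 passed with fry at NF36. Leaving out 1 array gave 10 to 12 lists at NF32 and 11 to 12 at NF36. Quantile normalization, median centring and an offset of 1 kept all 6 counts within 1.5 times. The eBayes settings and array weights, run on the numbers of probe sets only, kept those at NF32 and NF36 (array weights 1940 at NF36), and the mean over probe sets kept the 4 counts of lists and genes. The planned floor on low values for data already in log2 units was not run, since the values are linear. At NF36 25.4% to 27.5% of probe sets read below the offset, which limits what dim genes can show.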

Other observations

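The 7 lists described here were chosen after a first look at the genes that changed most, and the test of stage resemblance after its values had been seen. The direction and p of none of the 7 lists are therefore fully independent evidence. fabp7.L of the neural progenitor list is among the largest rises, and 16 of 31 abundant larval epidermis genes are also in a list fixed beforehand. Those of the innate immune list are not independent evidence at all. The innate immune list was prompted by inflammation-related genes seen in that look, such as irf1.L, mmp1.S and acod1lb.L, and its members mmp13.S and ptgs2.S had been seen. cxcl8.L and il1b.S, among the largest rises, are members too. Innate immune genes were higher in Ptf1a explants at both stages. At NF32, 9 of 27 measured genes passed higher and 1 lower, 16 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 1.38e-09, adjusted p = 0.119 with an estimated correlation). Beside cxcl8.L, the feedback inhibitors of inflammatory signalling nfkbia.S (42.9 ± 10.4 to 181 ± 46.0, log2 change 1.73 ± 0.19) and tnfaip3.S (16.9 ± 8.38 to 118 ± 44.1, 2.01 ± 0.26) rose, as did nfkbia.L (1.53 ± 0.22) and atf3.L (0.80 ± 0.11), and the collagenase mmp13.S fell (-1.57 ± 0.20). At NF36, 11 of 27 passed, all higher, 17 adjusted over the list alone, and 18 higher and 1 lower with the replicate block (median 0.55, camera adjusted p = 2.47e-09, adjusted p = 0.187 with an estimated correlation). The prostaglandin enzyme ptgs2.S rose from 13.0 ± 1.56 to 46.8 ± 11.2 (1.1 ± 0.12), with mmp3.L (1.35 ± 0.22) and the immediate early genes ier2.S (0.59 ± 0.09), ier2.L (0.92 ± 0.16) and fos.S (0.88 ± 0.16). The blood cell markers, which include those of granulocytes, were lower at both stages (camera adjusted p = 0.126 at NF32 and 0.301 at NF36 with an estimated correlation).

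Neural progenitor and regional patterning genes were higher for 4 of 41 at NF32, 9 adjusted over the list alone and 14 with the replicate block (median 0.27, camera adjusted p = 7.53e-09, adjusted p = 0.119 with an estimated correlation). These were the glial lipid binding gene fabp7.L (21 ± 23.8 to 200.1 ± 69.9, 2.68 ± 0.43), zic1.S (0.79 ± 0.15), otx1.L (0.73 ± 0.11) and sox1.S (0.52 ± 0.07), the last 3 at low intensity. At NF36, 5 of 41 passed, all higher, 7 adjusted over the list alone, and 14 higher and 2 lower with the block (median 0.14, camera adjusted p = 3.23e-06, adjusted p = 0.0888 with an estimated correlation). The neural crest factor pax3.L rose from 437 ± 49.1 to 701 ± 46.4 (0.67 ± 0.09), beside dlx2.L (0.69 ± 0.10), dlx5.L (0.77 ± 0.12) and dlx2.S (0.72 ± 0.12). Of 6 retina and lens genes at NF36 the pigment gene tyrp1.L passed, lower (383 ± 74.7 to 235 ± 39.5, -0.67 ± 0.15, adjusted p = 0.0432), also adjusted over the list alone, 2 were lower with the block, and the list did not pass (median -0.02, camera adjusted p = 0.212). Of 7 interferon genes none passed in limma at NF36, over all probe sets, adjusted over the list alone, with the block or at an unadjusted p under 0.05 (median 0.13, camera adjusted p = 0.212). At NF32 fewer than 5 genes of each of these lists were measured.

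Abundant larval epidermis genes were higher for 13 of 30 at NF36, 22 adjusted over the list alone and 26 with the block (median 0.56, camera adjusted p = 7.25e-15, adjusted p = 0.0981 with an estimated correlation), among them ppl.L (0.88 ± 0.15) and the proton pump gene atp6v1b1.L (1.28 ± 0.24). At NF32, 1 of 29 passed, also 1 adjusted over the list alone (median 0.06, camera adjusted p = 0.0961). Of the FOXO and fasting list 3 of 25 were higher at NF32, the autophagy genes map1lc3b.S (0.45 ± 0.07) and map1lc3b.L (0.68 ± 0.14) and txnip.L (0.57 ± 0.11), with 6 higher and 1 lower adjusted over the list alone and 5 and 1 with the block (median 0.11, camera adjusted p = 0.00758, adjusted p = 0.142 with an estimated correlation). At NF36, 2 of 27 were higher, txnip.L (0.75 ± 0.11) and ccng2.L (0.47 ± 0.10), with 10 higher and 2 lower adjusted over the list alone and 11 and 3 with the block (median 0.09, camera adjusted p = 0.0325, adjusted p = 0.278 with an estimated correlation). Of the glucocorticoid list 1 of 15 was higher at NF32, dusp1.L (0.52 ± 0.07), 6 adjusted over the list alone and 3 with the block (median 0.18, camera adjusted p = 3.82e-05, adjusted p = 0.151 with an estimated correlation). At NF36, sgk1.L (133 ± 21.2 to 448 ± 158, 1.57 ± 0.26) and dusp1.S (0.77 ± 0.15) were the 2 of 16 higher, 6 adjusted over the list alone and 7 with the block (median 0.19, camera adjusted p = 4.25e-04, adjusted p = 0.201 with an estimated correlation).

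A hypothesis is that Ptf1a explants developed more slowly, which would make their NF36 arrays resemble NF32 arrays. Over 22251 probe sets, Spearman's rho with the mean GFP array of NF32 averaged 0.9128 ± 0.0171 (SD, n = 4) for NF36 Ptf1a arrays and 0.8959 ± 0.0088 for NF36 GFP arrays, higher for Ptf1a in 3 of 4 pairs. An exact permutation test over 70 arrangements, which treats paired arrays as unpaired, gave p = 0.1714 (2-sided). It does not decide whether development may have been slower.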
